A study of Bifidobacterium longum subsp. longum BBMN68 with 6 samples.

How the data were processed

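Total RNA from *Bifidobacterium longum* subsp. *longum* BBMN68 was extracted with TRIzol and sequenced on an Illumina platform, per the labels' protocols. The 6 libraries formed 2 groups by the medium given in the labels: 3 control libraries from MRS medium with 0.05% L-cysteine, and 3 libraries from the same medium with 0.075% oxgall. All cultures were anaerobic at 37 °C for 24 h, in late stationary phase per the labels. The labels did not say that the libraries of a group came from separate cultures, so p-values measured only the spread between these libraries, which may be technical.

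Per the file headers, the authors deposited an expected count and an FPKM value for each gene in each library. The submitters' processing notes name Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0. The role of each tool, the genome build and the annotation were not given in the sources used here. HTSeq returns whole counts by default, whereas the deposited expected counts were estimates, of which 98.6% to 99.1% per library were whole within 1e-06. The tool behind the expected counts was therefore left open. FPKM values were scaled by the authors for gene length and sequencing depth. The authors' deposited table of the comparison gives log2 fold changes, p-values, adjusted p-values and a mean expression signal per group. Its log2 fold changes and adjusted p-values were set beside the results here, and its group means were not used. No column with values per library was left without a sample (0 columns). No sequence or annotation of strain BBMN68 was used here.

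Expected counts were rounded to whole numbers, and a gene missing from a library's file was given a count of 0. Totals per library ranged from 2662153 to 3281637 counts over 1861 genes. Genes passed filterByExpr (at least 10 counts in a library of typical size in 3 libraries, at least 15 in total), which left 1660 genes. The test was the 2-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the group as the only term and Benjamini-Hochberg (BH) adjustment over the tested genes. A gene was called changed at an adjusted p under 0.05, and a call of 2-fold or more also needed an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were calculated back from the F statistic. Levels are CPM values as defined in edgeR, with TMM-scaled library sizes, as mean ± SD of 3 libraries. Quantities per library were compared by a 2-sided exact permutation test, which cannot go below p = 0.1 for 3 against 3 libraries.

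On counts simulated with the control means for both groups and the real library sizes and dispersions, the edgeR step ran on 1641 genes. It recovered 75.4% of genes changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 100% of those changed by 2. Of its calls, 3.78% were unchanged genes. DESeq2 recovered 64.2%, 86.6% and 98.5% for the same sizes. Far fewer genes were changed in the simulation than were called in the real data, in equal numbers up and down. These shares may therefore not hold for the real data. The set test called the simulated rising set and 0 of the random sets. Simulated genes varied independently and the random sets held unchanged genes only. This says nothing of false calls in lists whose genes vary together.

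Gene names came from the authors' nr and KEGG columns, with KEGG matches at an E value of at most 1e-30. Symbols came from the authors' table or, through shared protein accessions, from the RefSeq gene table of another strain (assembly ASM19655v1). That table held the protein accession of 434 of the 1861 genes, and 148 genes received a symbol. Where the nr and KEGG names point to different functions, both are given. The 39 gene lists (as name patterns), the rule for named genes and the alternatives below were fixed before the data were examined. Reading the matched names, and before any gene was tested, 140 list and gene pairs judged not to belong were taken out. These were judgements: BBMN68_RS03300 was taken out by its nr name although its KEGG name matched. BBMN68_RS04915 was kept by its KEGG name against its nr name. Lists with at least 3 tested genes (36 lists) were tested with camera in limma 3.58.1 (preset correlation 0.01, BH over the lists). For 29 of these 36 lists, the number of calls adjusted over the list alone equalled the number adjusted over all tested genes; the other lists are named with both numbers. The list of ribosomal and transfer RNA genes matched 0 genes, so the ribosomal RNA share was not analysed here.

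The rule for named genes took the 10 genes per direction with the largest log2 fold change among called genes whose groups did not overlap, with a mean of at least 50 counts in the higher group and a product name. It also took the rising and the falling member of each tested list with the smallest adjusted p (up to 4 in the direction of a list that passed), all members of the bile list and the 3 genes with the highest FPKM per group. This gave 110 genes. BBMN68_RS04730 and the HipA genes were chosen after their values were seen. Of the named genes, 3 had a count that was not whole (BBMN68_RS03560, BBMN68_RS00055 and ssrA). There were 4 sets of genes with identical counts in all libraries (11 genes), which were integrase and ATPase copies, and their values are uncertain.

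The alternatives were a replicate block, DESeq2 size factors, library size alone, quantile normalization entered as offsets (pseudocount 0.5), no filter, a mean FPKM of at least 50, limma voom, DESeq2 1.42.0, scaling without the 10 most abundant genes, an adjusted p under 0.01, a test against 2-fold, leaving out each library, and, for lists, an estimated correlation, ranks and fry. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables, permutations and plots.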

Results

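*Bifidobacterium longum* BBMN68 was grown for 24 h in MRS medium with L-cysteine, and RNA levels were compared between 3 libraries without and 3 libraries with 0.075% oxgall, which is dried ox bile. The comparison addressed how transcript levels of this gut bacterium differ after long exposure to bile salts. Expected counts totalled 2662153, 2838507 and 2662924 in the control libraries and 3094008, 3148218 and 3281637 in the oxgall libraries. Across the 1660 tested genes, Pearson correlations of log2(FPKM + 1) were 0.994 within the control group, 0.987 to 0.992 within the oxgall group and 0.877 to 0.896 between groups. The first principal component held 93.0% of the variance. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 2.07 to 6.07 within the control group and 12.3 to 18.5 within the oxgall group. Separate library preparations of a single culture could also exceed that noise, so the origin of the replicates stays open.

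With oxgall, the gene for xylose isomerase (BBMN68_RS08925), which converts xylose to xylulose, rose 207-fold, from 38.9 ± 1.90 to 8041 ± 536 TMM-scaled CPM (SD, n = 3). Choloylglycine hydrolase (BBMN68_RS02680), the bile salt hydrolase that splits the amino acid from conjugated bile salts, rose 7.30-fold, from 1021 ± 27.8 to 7456 ± 244 (SD, n = 3). Formate acetyltransferase (BBMN68_RS03480), which splits pyruvate into acetyl-CoA and formate, rose 11.8-fold, from 4251 ± 124 to 50061 ± 2163 (SD, n = 3). A gene named fatty acid synthase by KEGG and ACP S-malonyltransferase by nr (BBMN68_RS07980) fell by 3.88 on the log2 scale, from 6812 ± 81.6 to 463.5 ± 21.7 (SD, n = 3). In all, 540 genes rose and 584 fell, and 536 did not pass (edgeR quasi-likelihood test, BH-adjusted p under 0.05). Of these, 185 rose and 221 fell at least 2-fold. The changed genes included 61 rising and 59 falling genes without a product name. The 2 groups did not overlap in 1174 genes (70.7%), where chance gives 10%. In each named gene that passed the test, all 3 oxgall libraries lay on the same side of all 3 control libraries. The naming rule required this of the largest changes and chose list members by their adjusted p, so it is no added evidence. Scaled by library size alone, which moved the median log2 fold change by -0.61, 213 genes rose and 1104 fell, so directions are relative to the scaling used. By library size alone more genes fell than rose in 34 of the 36 tested gene lists, and more rose in sugar uptake and the Clp proteases only.

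**Figure D1:**
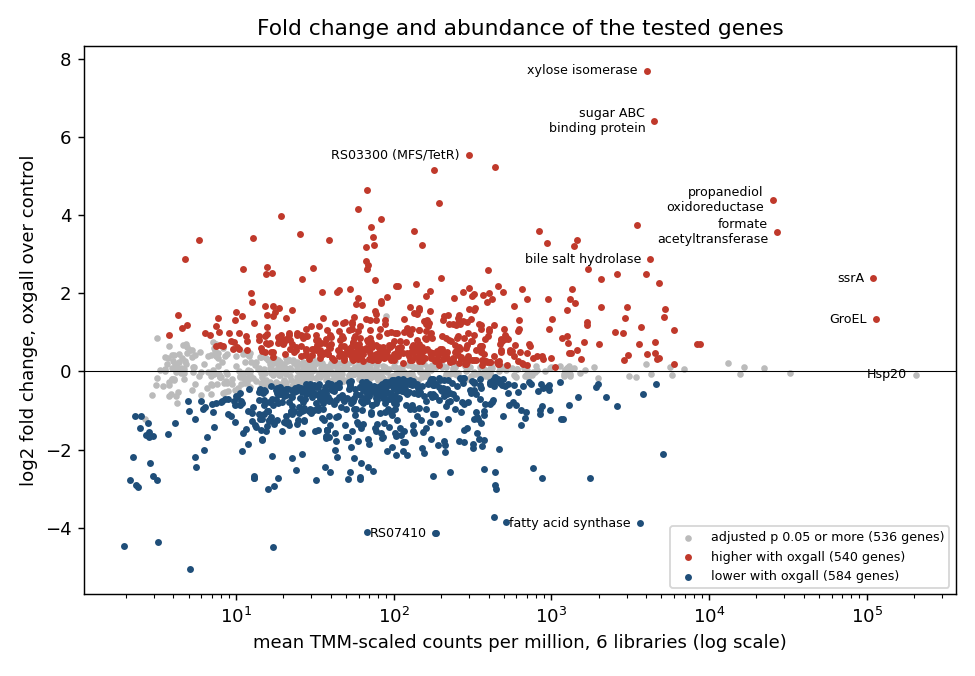
Log2 fold change (oxgall over control) of the 1660 tested genes against their mean TMM-scaled CPM on a log axis, with 540 rising genes in red, 584 falling genes in blue and 536 genes that did not pass in grey. Xylose isomerase is highest at 7.69, and ssrA, GroEL and Hsp20 are the most abundant.

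A few transcripts made up much of each library. Hsp20 (BBMN68_RS06620), a small heat shock chaperone, took 26.1 ± 1.39% of the counts in control and 16.03 ± 1.40% with oxgall (SD, n = 3; exact permutation p = 0.1, the smallest possible). The share of ssrA, by its symbol the transfer-messenger RNA that rescues stalled ribosomes and by nr a hypothetical protein, was 4.37 ± 0.13% in control and 14.9 ± 0.42% with oxgall (SD, n = 3; exact permutation p = 0.1). The 10 most abundant genes took 52.6 ± 1.27% and 60.3 ± 2.38% (SD, n = 3; exact permutation p = 0.1), and the median FPKM was 71.8 ± 2.63 and 42.6 ± 2.68 (SD, n = 3; exact permutation p = 0.1). After TMM scaling ssrA rose by 2.38 ± 0.11 (SE) on the log2 scale, with an adjusted p of 2.18e-10 by edgeR. Hsp20 had a log2 fold change of -0.088 ± 0.14 (SE) and an adjusted p of 0.589 by edgeR; by library size alone it fell by 0.70 on the log2 scale. GroEL (BBMN68_RS00220), the large chaperonin, rose by 1.33 ± 0.12 (SE) on the log2 scale with an adjusted p of 3.06e-07 by edgeR. Under quantile normalization, which sets levels by rank, its log2 fold change was -0.53, because ssrA passed it in every oxgall library. In no other alternative did its direction turn.

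Of the 2 genes on the bile list, the bile salt hydrolase rose (log2 fold change 2.87 ± 0.07, adjusted p = 1.34e-13 by edgeR). BBMN68_RS04265, a sodium transporter by nr and a bile acid:Na+ symporter by KEGG, had a log2 fold change of 0.17 ± 0.08 and an adjusted p of 0.0734 by edgeR. Without oxgall replicate 2 that adjusted p was 0.00154, with DESeq2 size factors it was 0.0470, and by library size alone the log2 fold change was -0.44. Among 25 multidrug and drug efflux genes, 4 rose, 9 fell and 12 did not pass, with 12 calls adjusted over the list alone and no pass as a set (camera adjusted p = 0.814). By library size alone 2 rose and 18 fell. With the matches removed by hand kept, 62 genes had a median log2 fold change of -0.12, and 19 rose and 23 fell (camera adjusted p = 0.903). BBMN68_RS09300, an MFS transporter that KEGG calls a tetracycline antiporter, rose by 3.25 on the log2 scale, and the multidrug ABC gene BBMN68_RS07445 fell by 1.45 on the log2 scale. BBMN68_RS03300 rose by 5.53 ± 0.10, from 12.6 ± 1.02 to 585.4 ± 40.3 CPM (SD, n = 3). KEGG calls it an MFS transporter of the lincomycin resistance type and nr a TetR regulator, and it was not counted in the list.

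Among 10 Clp and related protease genes, 6 rose, 0 fell and 4 did not pass, with a median log2 fold change of 0.53 that was -0.076 by library size alone. By edgeR 1 of them fell at an unadjusted p under 0.05, and 0 fell by DESeq2 or limma voom. The set test gave an adjusted p of 0.0374 (camera), and the adjusted p was 0.532 with an estimated correlation. It was 0.0522 without control replicate 3, 0.0620 by library size alone, 0.0680 under quantile normalization, 0.0505 with a mean FPKM of at least 50 and 0.0516 with all list matches kept. The gene BBMN68_RS08815, the membrane protease FtsH by KEGG and an AAA ATPase by nr, rose by 2.37 ± 0.06. The proteolytic subunit genes clpP and BBMN68_RS03445 rose by 1.177 and 1.188, and BBMN68_RS00260, ClpX by nr and ClpC by KEGG, rose by 1.41. Of 11 chaperone and heat shock genes, 5 rose, 1 fell and 5 did not pass; the median log2 fold change was -0.050, whereas the mean was 0.37 and the set test pointed up (camera adjusted p = 0.384). By library size alone 2 rose and 6 fell, and under quantile normalization 3 rose, 6 fell and the set test pointed down. With the matches removed by hand kept, 15 chaperone and heat shock genes had a median of 0.41, and 9 rose and 1 fell (camera adjusted p = 0.322). HtpX (BBMN68_RS06475) rose by 1.41 and GrpE (BBMN68_RS06345), the nucleotide exchange factor of DnaK, fell by 0.33 on the log2 scale.

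Of 46 sugar uptake genes tested, 33 rose, 6 fell and 7 did not pass (21 rose and 11 fell by library size alone), with a median log2 fold change of 0.87 (camera adjusted p = 9.67e-06, and adjusted p = 0.532 with an estimated correlation). BBMN68_RS08870, an ABC substrate-binding protein that KEGG assigns to sugar transport, rose by 6.42 ± 0.13, from 104.0 ± 9.51 to 8900 ± 1384 CPM (SD, n = 3). The ATP-binding gene BBMN68_RS08875, named for xylose by nr, rose by 4.32 ± 0.20, and a galactoside permease (BBMN68_RS00780) by 2.505 ± 0.07. The sugar ABC genes BBMN68_RS00385 and BBMN68_RS00390 rose by 2.03 and 1.97, and the substrate-binding gene BBMN68_RS05915 fell by 1.53 on the log2 scale. Outside this list, xylulokinase (BBMN68_RS08950), which follows xylose isomerase in xylose use, rose by 5.24 ± 0.10, and a sugar kinase that KEGG calls ribokinase (BBMN68_RS09295) rose by 3.98 ± 0.23. Of 42 glycoside hydrolase genes, 14 rose, 15 fell and 13 did not pass (5 rose and 27 fell by library size alone, and 16 rose and 14 fell under quantile normalization); the median log2 fold change was -0.059, the mean was -0.051 and the set test pointed up (camera adjusted p = 0.986). BBMN68_RS00775, a sucrose-6-phosphate hydrolase by nr and beta-fructofuranosidase by KEGG, rose by 2.50, and the family 43 hydrolase BBMN68_RS07385 fell by 1.98 on the log2 scale. Glycogen metabolism had 5 tested genes, of which 2 rose, 2 fell and 1 did not pass (camera adjusted p = 0.812). Glucose-1-phosphate adenylyltransferase (BBMN68_RS03015) rose by 1.33.

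In glycolysis, the bifid shunt and pyruvate metabolism, 17 of 30 genes rose, 6 fell and 7 did not pass. Their median log2 fold change was 0.35, or -0.26 by library size alone. The set test gave an adjusted p of 0.0133 (camera), and the adjusted p was 0.532 with an estimated correlation, 0.0620 by library size alone (7 rose and 14 fell), 0.0505 with a mean FPKM of at least 50 and 0.647 under quantile normalization. Among the rising members with the smallest adjusted p, formate acetyltransferase rose by 3.56 ± 0.09, its activating protein (BBMN68_RS03475) by 2.60 ± 0.07, phosphate acetyltransferase (BBMN68_RS03640) by 1.77 ± 0.06 and adhE, the acetaldehyde and alcohol dehydrogenase, by 1.182 ± 0.06. The falling member with the smallest adjusted p, the pentose phosphate isomerase gene rpiA, fell by 0.78 on the log2 scale. BBMN68_RS08770, a propanediol oxidoreductase by nr and lactaldehyde reductase by KEGG, rose by 4.39 ± 0.10, from 2313 ± 141 to 48466 ± 3771 CPM (SD, n = 3). Among 19 redox and oxidative stress genes, 13 rose, 4 fell and 2 did not pass, with a median of 0.56, or -0.050 by library size alone (camera adjusted p = 0.0374, and adjusted p = 0.532 with an estimated correlation). Leaving out control replicate 3 or oxgall replicate 1, 2 or 3 raised that adjusted p to between 0.0503 and 0.0948, and it was 0.164 by library size alone (6 rose and 7 fell), 0.0949 with a mean FPKM of at least 50, 0.0816 with DESeq2 and 0.101 with all list matches kept. BBMN68_RS07795, NADH oxidase by KEGG and a disulfide oxidoreductase by nr, rose by 2.19, and sufC and sufD, iron-sulphur cluster assembly genes by KEGG and ABC transporter parts by nr, rose by 1.08 and 0.83. A gene that KEGG calls dihydrolipoamide dehydrogenase and nr a disulfide oxidoreductase (BBMN68_RS08515) rose by 1.03, and a methionine sulphoxide reductase (BBMN68_RS06595), which repairs oxidized methionine, fell by 1.23 on the log2 scale. The F0F1 ATPase list had 8 tested genes, of which 1 rose, 5 fell and 2 did not pass (camera adjusted p = 0.376, but 0.0317 under quantile normalization). Its epsilon subunit gene (BBMN68_RS05640) fell by 0.997 on the log2 scale, and atpB rose by 0.28, with -0.33 by library size alone and an adjusted p of 0.0866 under quantile normalization.

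**Figure D2:**
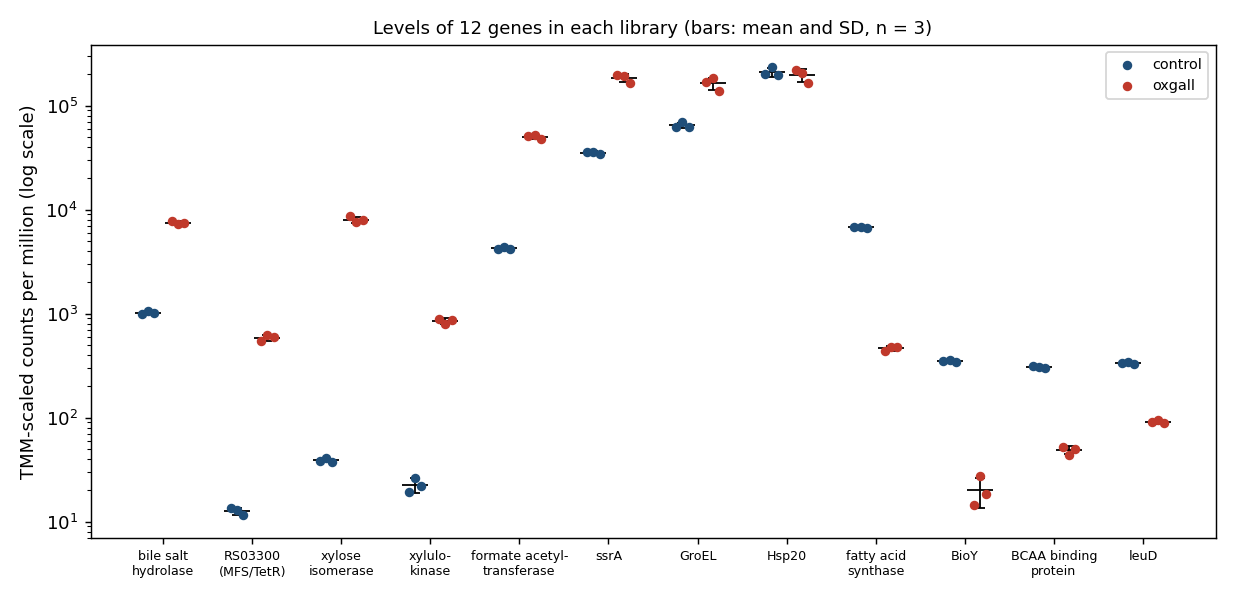
TMM-scaled CPM (log axis) of 12 genes in each of the 3 control (blue) and 3 oxgall (red) libraries, with the mean and SD as bars. The groups are apart for every gene shown except Hsp20. GroEL, higher with oxgall here, has a log2 fold change of -0.53 under quantile normalization, where it loses rank to ssrA, and turns in no other alternative.

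Of 11 branched-chain amino acid synthesis genes, 0 rose, 7 fell and 4 did not pass, with a median log2 fold change of -0.86 (camera adjusted p = 0.00467, and adjusted p = 0.532 with an estimated correlation). By edgeR 1 of them rose at an unadjusted p under 0.05, by DESeq2 1 rose and by limma voom 0 rose. The leucine pathway gene leuD fell by 1.87 on the log2 scale, from 334.7 ± 4.97 to 91.3 ± 3.63 CPM (SD, n = 3), and the large subunit of the same isomerase (BBMN68_RS07780) fell by 1.76. Acetolactate synthase (BBMN68_RS05325), the entry step to valine and leucine, fell by 1.22, and the branched-chain aminotransferase (BBMN68_RS02940) fell by 1.183. In amino acid transport, 9 of 33 genes rose, 22 fell and 2 did not pass, with a median of -0.67 (camera adjusted p = 0.00467, and adjusted p = 0.532 with an estimated correlation). By library size alone 0 rose and 25 fell. The branched-chain amino acid ABC genes BBMN68_RS08980, BBMN68_RS09000 and BBMN68_RS08995 had log2 fold changes of -2.66, -2.57 and -2.44. The amino acid transporter BBMN68_RS07415 and the neighbouring tag BBMN68_RS07410, an ABC permease, had log2 fold changes of -4.11 ± 0.16 and -4.14 ± 0.12. BBMN68_RS04725, a polar amino acid binding protein by KEGG and an ABC substrate-binding protein by nr, rose by 0.57, with -0.036 by library size alone.

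Peptide uptake and peptidase genes numbered 29 tested, of which 8 rose, 16 fell and 5 did not pass. Their median log2 fold change was -0.62 (camera adjusted p = 0.0234, and adjusted p = 0.532 with an estimated correlation), and the adjusted p was 0.176 with camera on ranks, 0.102 under quantile normalization, 0.0929 with a mean FPKM of at least 50 and 0.167 with limma voom. With the matches removed by hand kept, 39 genes had a median of -0.086, 14 rose and 19 fell, and the adjusted p was 0.106. BBMN68_RS04645 and BBMN68_RS04540, peptide/nickel and oligopeptide binding proteins by KEGG, had log2 fold changes of -3.02 and -2.06. BBMN68_RS07850 and BBMN68_RS03370, peptide ABC genes by nr and ABC ATP-binding proteins without a named substrate by KEGG, had -2.90 and -2.51. The Xaa-Pro aminopeptidase gene (BBMN68_RS01230) rose by 1.57. Among 31 histidine, aromatic and lysine-threonine synthesis genes, 3 rose, 18 fell and 10 did not pass, with 22 calls adjusted over the list alone (camera adjusted p = 0.0797, but 0.0306 under quantile normalization, 0.0148 with limma voom and 0.0184 on ranks). In that list hisB fell by 1.73 on the log2 scale, and BBMN68_RS09270, a tryptophan pathway isomerase, rose by 3.23. Outside this list, dihydrodipicolinate reductase (BBMN68_RS02875), which acts in lysine synthesis, rose by 4.64 ± 0.13 from 5.16 ± 0.20 CPM. In glutamine, arginine and nitrogen metabolism, 6 of 23 genes rose, 15 fell and 2 did not pass (camera adjusted p = 0.155, but 0.0306 under quantile normalization, 0.0475 with limma voom and 0.0372 on ranks), with glutamine synthetase adenylyltransferase (BBMN68_RS02675) up by 1.66 and N-acetylglutamate synthase (BBMN68_RS04100) at -1.45.

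In fatty acid and membrane lipid synthesis, 3 of 14 genes rose, 5 fell and 6 did not pass, with a median log2 fold change of -0.065, a mean of -0.63 and a set test adjusted p of 0.0501 (camera). Without control replicate 1 or 2 or oxgall replicate 1 the adjusted p was 0.0464, 0.0435 and 0.0456, and over the camera alternatives it ranged from 0.0132 with DESeq2 to 0.797 on ranks. With fry, which tests another hypothesis, it was 2.72e-05. The fatty acid synthase gene stands beside 3 other tags that fell steeply. BBMN68_RS07975, a carboxyltransferase that KEGG calls propionyl-CoA carboxylase beta chain, had a log2 fold change of -3.86 ± 0.09. BBMN68_RS07970, a carboxylate-amine ligase by nr and an acetyl-CoA and propionyl-CoA carboxylase by KEGG, had -3.71 ± 0.07, and BioY (BBMN68_RS07965), for the uptake by KEGG or synthesis by nr of biotin, the cofactor of such carboxylases, had -4.12 ± 0.12. Cyclopropane-fatty-acyl-phospholipid synthase (BBMN68_RS08765), which modifies membrane fatty acids, rose by 1.998 ± 0.06. Of 26 peptidoglycan synthesis genes, 8 rose, 14 fell and 4 did not pass (camera adjusted p = 0.384), and by library size alone 20 fell. BBMN68_RS07020, a lipid II flippase by KEGG and a virulence factor of the MviN family by nr, fell by 1.82 on the log2 scale. Among 21 exopolysaccharide and glycosyl transfer genes, 3 rose, 13 fell and 5 did not pass (camera adjusted p = 0.192, but 0.0467 under quantile normalization and 0.0499 on ranks), and BBMN68_RS05060, a capsular exopolysaccharide protein by nr and a protein-tyrosine kinase by KEGG, fell by 1.32 on the log2 scale. The 16 pili, sortase and surface genes had 4 that rose, 8 that fell and 4 that did not pass (camera adjusted p = 0.532). A fimbrial gene (BBMN68_RS07145) fell by 1.08 on the log2 scale, and a wall-anchored endo-alpha-N-acetylgalactosaminidase (BBMN68_RS06090), a glycosidase rather than a pilus part, rose by 1.59.

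Of 50 ribosomal protein genes, 8 rose, 5 fell and 37 did not pass, with 10 calls adjusted over the list alone and a median log2 fold change of 0.080 that was -0.53 by library size alone and -0.089 under quantile normalization (camera adjusted p = 0.814). By library size alone 3 rose and 45 fell, and under quantile normalization 5 rose and 20 fell. Among them rpsB rose by 1.001 and rpsT fell by 0.78 on the log2 scale. Aminoacyl-tRNA synthetases had 2 of 19 that rose, 13 that fell and 4 that did not pass (camera adjusted p = 0.167, but 0.00137 under quantile normalization, 0.0208 with limma voom and 0.0192 on ranks), with leuS, which charges leucine, falling by 0.99 on the log2 scale. The call of threonyl-tRNA synthetase (BBMN68_RS02105), 1 of the 2 that rose, was lost when control replicate 1, 2 or 3 or oxgall replicate 3 was left out (adjusted p 0.0731, 0.0886, 0.0513 and 0.0697), under quantile normalization (0.582) and with a mean FPKM of at least 50 (0.239). Of 12 translation factors, 4 rose, 4 fell and 4 did not pass (camera adjusted p = 0.986), against 1 up and 11 down by library size alone and 3 up and 7 down under quantile normalization, with frr up by 0.87 and infB at -0.40. In transcription and sigma factors, 6 of 11 genes rose, 1 fell and 4 did not pass (camera adjusted p = 0.384), against 2 up and 7 down by library size alone and 4 up and 4 down under quantile normalization. The elongation factor GreA (BBMN68_RS03845) rose by 1.35, and rpoZ fell by 0.38 on the log2 scale.

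**Figure D3:**
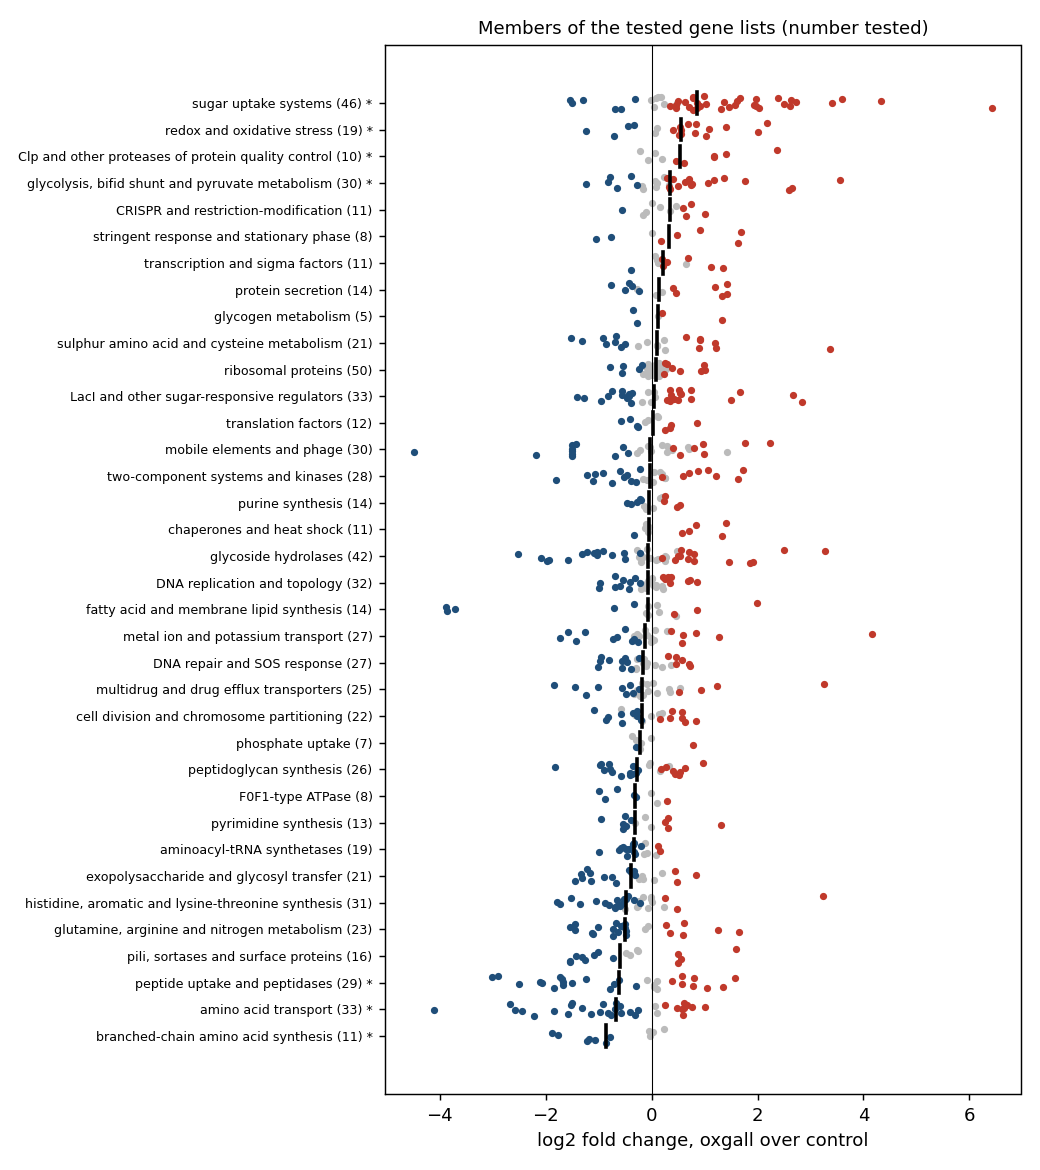
Log2 fold change (oxgall over control) of each tested member of the 36 tested lists, in red where it rose, blue where it fell and grey where it did not pass, with the list's median as a black bar and the number tested in parentheses. Asterisks mark the 7 lists that passed camera with a preset correlation; with an estimated correlation 0 passed, and 1 list had an unadjusted p under 0.05. By library size alone the medians of the Clp, glycolysis and redox lists are -0.076, -0.26 and -0.050.

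An adjusted p under 0.05 was given to 1005 genes in the authors' deposited table, 514 up and 491 down. Of the genes called here, 995 were also called in the authors' deposited table, 0 of them with the opposite sign, and 129 were called here alone. Another 3 tested genes and 7 genes not tested here were called in the authors' deposited table alone. Across the 1660 genes, which are not independent replicates, log2 fold changes here and in the authors' deposited table had a Pearson correlation of 0.997. Both come from the same libraries, so the table is no independent evidence.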

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

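Keeping all list matches, and putting BBMN68_RS03300 back in the efflux list, were chosen after seeing the data; the other alternatives were planned. Of 110 named genes, 97 were tested in every alternative, and 86 of these kept direction and call throughout; the other 13 were not tested with a mean FPKM of at least 50. An adjusted p under 0.01 and the test against 2-fold were applied to the counts of genes only. With a mean FPKM of at least 50, fewer genes were tested (919), and 726 changed (355 up, 371 down), 236 at least 2-fold (118 up, 118 down). By library size alone 213 rose and 1104 fell (90 and 497 at least 2-fold), from the shift of -0.61. A test against 2-fold, stricter by construction, called 144 falling genes. Other alternatives gave counts within 1.5 times, with 1037 to 1114 changed genes when a library was left out. DESeq2 called 1003 of 1824 genes. By library size alone the log2 fold changes turned to -0.33 (atpB), -0.10 (BBMN68_RS01255), -0.45 (BBMN68_RS02105), -0.12 (BBMN68_RS02160), -0.30 (BBMN68_RS00290), -0.036 (BBMN68_RS04725) and -0.44 (BBMN68_RS04265), and each was higher by less than the shift before. The calls of nrdD (0.11), phoU (0.18) and BBMN68_RS07130 (0.24) were lost there. More genes fell than rose there in 9 lists in which more rose in the main analysis: chaperones, glycolysis, redox, ribosomal proteins, transcription, stringent response, secretion, CRISPR and LacI regulators. GroEL (BBMN68_RS00220) turned to -0.53 under quantile normalization, which sets levels by rank, and kept its direction and call in every other alternative. It stood above ssrA in every control library (means 64965.5 and 35378.6 CPM) and below ssrA in every oxgall library (means 163610 and 184775 CPM). The turn goes with this loss of rank to ssrA, and is no sign of a lower GroEL level. Hsp20 (BBMN68_RS06620), not called, ranged from -0.18 to 0.042 when a library was left out. Passing lists numbered 7, against 4 by library size alone, 3 with a mean FPKM of at least 50, 0 with an estimated correlation, 27 with fry, which tests another hypothesis, and 4 with all matches kept; apart from fry the cause was not tested. Sugar uptake, branched-chain synthesis and amino acid transport lost their call with the estimated correlation only. Over all alternatives the adjusted p reached 0.647 for glycolysis and 0.532 for the other lists. The 0.532 is a single value that BH gave to all 7 lists. Their unadjusted camera p with an estimated correlation ran from 0.0152 (amino acid transport) to 0.145 (sugar uptake). Amino acid transport weakened although its estimated correlation, -0.0090, was under the preset 0.01. Its unadjusted camera p was 0.000389 with the preset. The histidine, aromatic and lysine-threonine list, at 0.0098, went from an unadjusted camera p of 0.0199 to 0.0798. A correlation above the preset thus does not account for the weaker result of these lists, and the 0.532 does not measure correlation alone. In the other passing lists the estimated correlation was above the preset, from 0.050 (glycolysis) to 0.27 (branched-chain synthesis). With BBMN68_RS03300 back, the efflux list had 5 rising and 9 falling genes of 26 (adjusted p = 0.870). Same-numbered libraries deviated with correlations of -0.003, -0.067 and 0.023, and 1 of 6 libraries correlated best with its own number. The numbers thus gave no pairing. A replicate block called 1100 genes (533 up, 567 down; 403 at least 2-fold) and changed no call of a named gene or list. Pseudocounts for FPKM and a test on recovered reads were not run, since counts were given. Leaving out ribosomal RNA removed no gene.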

Other observations

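With TMM scaling, several functions not yet described moved in both directions. Among 14 purine synthesis genes, 4 rose, 5 fell and 5 did not pass, with 10 calls adjusted over the list alone, against 12 that fell by library size alone, 5 up and 3 down with DESeq2 size factors and 5 up and 4 down without the 10 most abundant genes; the median log2 fold change was -0.040, whereas the mean was 0.0072 and the set test pointed up (camera adjusted p = 0.998). Of 13 pyrimidine genes 4 rose, 6 fell and 3 did not pass (camera adjusted p = 0.814), with BBMN68_RS04915, dihydroorotate dehydrogenase by KEGG and diguanylate cyclase by nr, up by 1.30. Sulphur amino acid and cysteine genes had 7 of 21 rising, 8 falling and 6 not passing (camera adjusted p = 0.812). In that list LuxS (BBMN68_RS04600), which makes the precursor of a signalling molecule, rose by 1.22, and BBMN68_RS03510, a methionine binding protein by KEGG and an ABC substrate-binding protein by nr, fell by 1.32 on the log2 scale. Of 8 stringent response and stationary phase genes 5 rose, 2 fell and 1 did not pass (camera adjusted p = 0.419). A universal stress protein (BBMN68_RS00255) rose by 1.69, and the (p)ppGpp synthetase gene (BBMN68_RS01670), whose product makes the starvation alarmone, fell by 1.04 on the log2 scale. LacI and other sugar-responsive regulators had 15 of 33 rising, 13 falling and 5 not passing (camera adjusted p = 0.827), and the NagC-type genes BBMN68_RS01185 and BBMN68_RS08855, which KEGG calls glucokinase, had log2 fold changes of 1.495 and -0.82. Metal ion and potassium transport had 6 of 27 rising, 10 falling and 11 not passing (camera adjusted p = 0.814). The permease gene BBMN68_RS09255, a cobalt transporter by nr and part of an energy-coupling factor system by KEGG, rose by 4.17 ± 0.15 (SE), and a manganese transporter (BBMN68_RS05080) fell by 1.58 on the log2 scale. Phosphate uptake had 1 rising, 1 falling and 5 other genes, with 1 call adjusted over the list alone. The call of the falling BBMN68_RS03220 (-0.30) was lost with DESeq2, DESeq2 size factors, quantile normalization and without control replicate 1 or 2 or oxgall replicate 1 or 3 (-0.18 and adjusted p 0.263 without the last), and that of the rising phoU by library size alone. The list's median was -0.22, its mean was -0.088 and the set test pointed up (camera adjusted p = 0.986). The hded gene BBMN68_RS09070 rose by 5.16 ± 0.13 (SE), from 9.82 ± 1.67 to 351.1 ± 38.8 CPM (SD, n = 3).

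The counts of the lists that follow depend on the scaling, and by library size alone 20 DNA repair, 28 DNA replication and 15 cell division genes fell. With TMM scaling, DNA repair had 6 of 27 genes rising, 10 falling and 11 not passing (camera adjusted p = 0.812), with UvrC (BBMN68_RS01985) at -0.80. DNA replication had 8 of 32 rising, 10 falling and 14 not passing (camera adjusted p = 0.814), with the anaerobic reductase gene nrdD up by 0.73 (0.11 by library size alone, where its call was lost). Cell division and partitioning had 7 of 22 rising, 9 falling and 6 not passing, with 17 calls adjusted over the list alone (camera adjusted p = 0.814), and FtsQ (BBMN68_RS01090) fell by 1.09 on the log2 scale. Two-component systems and kinases had 8 of 28 rising, 12 falling and 8 not passing, with 21 calls adjusted over the list alone (camera adjusted p = 0.986). The histidine kinase BBMN68_RS03355 fell by 1.80 on the log2 scale, and BBMN68_RS00235, a response regulator by KEGG and alkaline phosphatase by nr, rose by 1.64. Protein secretion had 6 of 14 rising, 5 falling and 3 not passing (camera adjusted p = 0.601), with FtsY (BBMN68_RS05975) up by 1.20. CRISPR and restriction genes had 4 of 11 rising, 1 falling and 6 not passing (camera adjusted p = 0.812), with Cse1 (BBMN68_RS09335) up by 1.02. Mobile elements had 7 of 30 rising, 11 falling and 12 not passing (camera adjusted p = 0.814). Of those that fell, 5 integrase genes, BBMN68_RS00055 among them, had identical counts and may share reads, so that their common log2 fold change of -1.49 is uncertain. The -4.48 of the integrase BBMN68_RS03560 is uncertain too, since its counts were not all whole. Its oxgall libraries had 0, 4.47 and 0 CPM, so the size of its fall rests on reads in 1 oxgall library. Of the 2 toxin-antitoxin genes, both HipA, BBMN68_RS01685 fell by 2.13 on the log2 scale and BBMN68_RS09565 had -1.22 with an adjusted p of 0.0729 by edgeR. With the matches removed by hand kept, that list had 14 genes, of which 5 rose and 4 fell (camera adjusted p = 0.903). The competence gene ComEA (BBMN68_RS09530) fell by 3.01 on the log2 scale.

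Of the tests that follow, those of gene length and of short genes were set before their result was seen, and the others were chosen after the result was seen. The first pattern is the breadth of the change, 1124 of 1660 genes. A few genes taking most of the counts would shift the other genes by a common factor, but each of 5 scalings left at least 90 genes changed 2-fold or more in each direction, which argues against it as the whole cause. Coding length is argued against by a Spearman correlation of -0.064 with the log2 fold change across genes. A different stage of growth with oxgall stays open, since no file measures growth and the ribosomal protein median of 0.080, near 0 over genes that went both ways, decides nothing; the response to oxgall stays open with it. Of the 10 splits of the 6 libraries only the real split (1 of 10) reached its 1124 genes, 406 genes at 2-fold or more and 7 lists. The highest other split gave 0, 0 and 4 (by edgeR at an unadjusted p under 0.05 at most 16 genes, and at most 1 at 2-fold or more). Every other split mixed control and oxgall libraries in both groups, which widened the spread within groups. Their low counts are therefore no rate of false calls, and 10 splits are too few for a share under 0.05.

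The next pattern is ssrA, which rose by 2.38 on the log2 scale. A preference for short genes in the oxgall libraries is argued against: the 138 other tested genes listed at no more than the 397 bases of ssrA had a median log2 fold change of 0.062, with a 95% bootstrap interval of -0.061 to 0.16. Less messenger RNA per cell could also raise the share of this stable RNA, and its rise of 1.77 by library size alone fits both this and a change of ssrA itself, which cannot be told apart because no file measures RNA per cell. BBMN68_RS04730, the SsrA-binding protein by KEGG and a single-stranded DNA-binding protein by nr, rose by 3.60 ± 0.06 (SE), from 128.0 ± 1.96 to 1548 ± 9.16 CPM (SD, n = 3). That gene was chosen after its value was seen, and a change of the ssrA system with oxgall is an untested hypothesis that stays open.

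The last pattern, noticed in the list of largest changes before it was tested, is that genes with neighbouring locus tags moved together. Of 728 pairs of called genes with consecutive tags, 78.2% moved in the same direction, against a mean of 50.1% and at most 56.6% in 10000 shuffles (permutation p = 0.0001, the smallest they can give). Among 68 pairs that neighbour each other in the reference strain the share was 79.4%, against at most 72.1% in the shuffles. These pairs come from the same called genes, and pairs found by both rules were not removed, so they are no separate evidence. Shared transcription of neighbouring genes may explain this, as a hypothesis, since strand was not used here and the planned test within a strand was not run. There were 7 runs of at least 5 consecutive tags changed 2-fold or more in the same direction, among them 11 rising genes from BBMN68_RS09250 to BBMN68_RS09300 (median 3.45) and 10 falling genes from BBMN68_RS05025 to BBMN68_RS05070 (median -1.34) around BBMN68_RS05060. The rising run holds BBMN68_RS09255, BBMN68_RS09270, BBMN68_RS09295 and BBMN68_RS09300, named above under separate functions, so their rises may not be separate changes. Another run of 5 falling genes, from BBMN68_RS08980 to BBMN68_RS09000 (median -2.44), holds the branched-chain amino acid ABC genes named above. Their falls may likewise not be separate changes.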
